A study of Mus musculus with 10 samples.

How the data were processed

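RNA-seq and ATAC-seq, an assay of open chromatin by insertion of sequencing adapters with the Tn5 transposase, were measured in C3H10 T1/2 cells, a mouse embryo fibroblast line with mesenchymal properties. The RNA-seq set held 3 static control libraries and 3 libraries from cells under cyclic mechanical strain. The ATAC-seq set held 2 libraries from GFP control cells and 2 from cells with a CRISPR/Cas9 knockout of Piezo1. Per the labels' protocols, RNA-seq cells were grown for 48 h on flexible collagen-coated plates before a sinusoidal strain of 0.5 Hz and 10% elongation was applied for 8 h per day over 3 days. Per the labels' protocols, cDNA was amplified with a full-length single-cell kit and sequenced as paired reads of 150 bases, and ATAC-seq nuclei came from 50000 cells by the Omni-ATAC procedure. Amplified cDNA carries no molecular identifiers in the sources used here, so reads need not be independent molecules. The labels do not say whether replicates came from separate cultures, so p-values measure the spread between these libraries, which may be technical.

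The authors deposited 1 table of read counts per gene symbol for the RNA-seq libraries, which the values show to be whole numbers with a different total in each library. Per the submitters' processing notes, reads were trimmed with Trim Galore 0.6.5, aligned with STAR to mm10 and counted with HTSeq, and DESeq2 is named as well. The versions of STAR and HTSeq, the gene annotation, the strand setting and the handling of reads that map to several places are not given in the sources used here. Reads of ribosomal protein genes and other families with near-identical copies or pseudogenes could be split among copies by such counting. Reads of overlapping genes on opposite strands cannot be told apart if counting ignored the strand. Values of all these genes are therefore uncertain. For ATAC-seq the authors deposited 1 peak list per library, with no pooling of replicates. Per the submitters' processing notes, Trim Galore 0.6.5, Bowtie2 2.4.2 and MACS2 were used with mm10, and the deposited lists are labelled as having blacklisted regions removed. The MACS2 version and threshold, duplicate removal and the shifting of reads to the transposase cut are not given in the sources used here. In the deposited peak lists each peak has a fold enrichment, which is a ratio to the local background of its own library, and the authors' −log10 p and −log10 q values. Those peak values were used only to describe, rank and filter peaks within a list. The read depth of the ATAC-seq libraries is unknown from peak lists.

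The count table held 46095 gene symbols and no rows outside genes. Of these, 41483 matched the symbol and 1057 a synonym in a RefSeq gene table of the GRCm38.p6 assembly, which is the mm10 build, and 3555 matched neither. Library totals lay between 36150738 and 41024689 counts. The chi-square per degree of freedom between replicates was 9.78 or more, so no replicate pair agreed within sampling noise.

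Strain and control were compared with edgeR 4.0.16 (glmQLFit and glmQLFTest, two-sided) in R 4.3.3 after TMM scaling and filterByExpr, which left 15335 genes. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. CPM values (counts scaled to a common library size) are TMM-scaled, and the standard error of a log2 fold change was the absolute log2 fold change divided by the square root of the F statistic. On data simulated for this comparison over 15335 genes, the test called 92.5% of 67 genes with a log2 change of 1, 29.9% of 67 with 0.5, and 100% of 66 with 2, and 3.27% of its calls were false. The changed genes were drawn only from genes above a minimum mean count, so these shares do not cover genes with fewer counts. No simulated library was made to stand apart from its group, so the shares may not hold for the real libraries. In all, 34 gene lists were fixed before the data were examined, and those with at least 5 tested members were tested with limma 3.58.1 camera, with a preset inter-gene correlation of 0.01 on log2 CPM with a prior count of 2. Camera with an estimated correlation and fry were run beside it. In the simulation the 1 raised list was called, as were 0 of 30 unchanged lists. Genes were simulated independently of one another, so this does not show how often lists of correlated genes are called in error. The estimated correlation of the real lists reached 0.84, for the interferon list.

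Peaks of the 4 libraries were merged with bedtools 2.31.1 where they overlapped by at least 1 bp, and a region was present in a library when a peak of that library overlapped it. Regions present in both libraries of a group and in neither of the other were counted, beside the other 2 ways to split 4 libraries into pairs. No test between the groups was made of the peak lists. On simulated peak lists with 5000 regions, the counts of regions in all libraries, control-only and knockout-only regions came to 100.2%, 103% and 109% of those built in, the excess being unrelated regions that appeared in that pattern at random. Every simulated library held all built-in regions of its class, so peaks missed in a shorter list were not simulated. Jaccard indices are shared over combined base pairs. A gene was assigned to a region within 5 kb of its body. Gene lists and genes changed under strain were set against genes near group-specific regions with two-sided Fisher's exact tests, with genes near any region found in both libraries of a group as background. The gene table gives gene ends and no strand or exons, so the test planned for transcription start sites could not be made. The share of regions within 1 kb of either end of a protein-coding gene was used in its place, a choice made after seeing the files. Positions are in mm10 and 1-based.

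The genes and regions named were set by a rule written before the data were examined. It took Piezo1. It took the 10 genes with the largest positive and the 10 with the largest negative log2 fold change among called genes with an average log2 CPM of at least 2 and no overlap of the groups' libraries, leaving out predicted, clone-named and pseudogene models. It took up to 4 called members of each list with the smallest p. For ATAC-seq it took every peak at Piezo1, the 5 group-specific regions per direction with the highest lower −log10 q of the pair, and up to 10 list genes per direction near such regions. Genes outside the rule are marked as such. Not every gene the rule took is named in the text.

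The alternatives fixed before the data were examined were RLE scaling, library size only, no filter, a minimum of 50 counts, the replicate number as a block, DESeq2 1.42.0, limma-voom, a minimum absolute log2 fold change of 1 and leaving out each library. For peaks they were a −log10 q of at least 5, lists of equal length (the 13610 strongest by q), a peak covering 50% of the region, windows of 250 bp on each side of the summits, leaving out each library, and gene windows of 50 kb. Alternatives added after seeing the data left out chromosomes 1, 8, 15, 16 and X, compared genes within 3 classes of gene length, and tested the gene lists near regions with lists of equal length.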

Results

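Gene expression under cyclic mechanical strain was measured by RNA-seq in 3 static control and 3 cyclic strain libraries of C3H10 T1/2 cells, and chromatin accessibility by ATAC-seq in 2 GFP control and 2 Piezo1 knockout libraries of the same line. The series' title concerns mechanical force, estrogen and the mechanically gated ion channel PIEZO1 in alveolar bone. Total counts were 38491897, 36150738 and 36305998 in control replicates 1 to 3 and 40023544, 37233101 and 41024689 in strain replicates 1 to 3. The ATAC-seq lists held 15978 and 26652 peaks in control replicates 1 and 2 and 15980 and 13610 peaks in knockout replicates 1 and 2. The 10 most abundant genes took 11.9% to 12.5% of the counts in control libraries and 9.87% to 10.7% in strain libraries.

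The first comparison asked which genes differ between static and strained cells. Piezo1 mRNA was 1.45-fold higher under strain, at 702 ± 65.7 CPM against 485 ± 86.2 CPM (SD, n = 3 each; log2 fold change 0.53, SE 0.14, adjusted p = 0.0313). Its values were 501, 563 and 392 CPM in control replicates 1 to 3 and 627, 728 and 751 CPM in strain replicates 1 to 3. The call was lost without control replicate 1 (0.56, adjusted p = 0.0902), strain replicate 2 (0.50, adjusted p = 0.0972) or strain replicate 3 (0.48, adjusted p = 0.118). Over all genes, 911 were higher and 1134 lower under strain among 15335 tested. Without control replicate 1 the counts were 369 and 610, without strain replicate 2 they were 420 and 661, and without strain replicate 3 they were 404 and 577. With library size alone as scaling, 1169 genes were higher and 935 lower, a share of 55.6% higher against 44.5% with TMM. Control replicate 3 stood apart from the other controls, with a chi-square per degree of freedom of 40.5 and 64.7 against replicates 1 and 2, which differed from each other by 9.78. Strain replicate 1 stood apart from strain replicates 2 and 3 (48.2 and 37.7), which differed from each other by 16.9.

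Among called genes with an average log2 CPM of at least 2 and libraries that did not overlap, and leaving out predicted, clone-named and pseudogene models, the largest increase was in Cyp1a1, the cytochrome P450 induced through the aryl hydrocarbon receptor, at 8.05 ± 0.788 CPM against 0.215 ± 0.147 CPM (SD, n = 3; log2 fold change 5.23, SE 0.35, adjusted p = 1.68e-05). Its summed counts were 967 under strain and 23 in control, a ratio of 39.4 (95% exact interval 26.1 to 62.5, counting error only). With 1 library left out its log2 fold change lay between 4.81 and 5.86, the latter without control replicate 3. The lipoprotein and reelin receptor gene Lrp8 rose 4.68-fold and the transporter gene Slc22a23 by a log2 fold change of 2.07. Fam110c rose 3.92-fold, the acute-phase gene Saa3 3.69-fold from 90.3 to 333 CPM, the quinone reductase Nqo1 3.44-fold, Dlgap2 3.41-fold, Mfsd6 3.21-fold and the BMP antagonist Grem1 3.20-fold. The adjusted p of each of these genes was 0.00135 or less.

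Among the same genes, the largest decrease was in Gipr, the receptor of the incretin GIP, which went from 10.3 ± 3.02 CPM to 0.0420 ± 0.0158 CPM (SD, n = 3). Its summed counts were 1125 in control and 5 under strain, a ratio of 0.00417 (95% exact interval 0.00135 to 0.00976, counting error only). Smtnl2 went from 11.1 to 0.130 CPM, with 1206 and 16 summed counts, a ratio of 0.0124 (95% exact interval 0.00709 to 0.0203, counting error only). Igfbp5, a binding protein of insulin-like growth factors, fell by 4.98 on the log2 scale (SE 0.35), from 26.2 to 0.842 CPM. With 1 library left out its log2 fold change lay between −5.59 (without strain replicate 2) and −4.58. The log2 fold change was −4.89 for the actin-bundling gene Espn, −3.40 for Ndrg2, −3.32 for the T-type calcium channel gene Cacna1h, −3.22 for Rtn4rl2, −3.16 for Syt5 and −2.98 for Tmem74b. Each of these genes had an adjusted p of 0.000199 or less.

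The 34 fixed gene lists were each described by their called members, and 32 of them had enough tested members for camera. At the preset correlation, 12 lists were called. Camera with an estimated correlation called 0 lists. Fry, which tests whether a list moves 1 way on balance, called 11, of which 9 were among the 12. The 9 other splits of the 6 libraries into 3 and 3, which mix the groups, each gave 0 called genes. At the preset correlation they still gave 4 to 14 called lists, so such a call alone does not tie a list to strain.

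**Figure D1:**
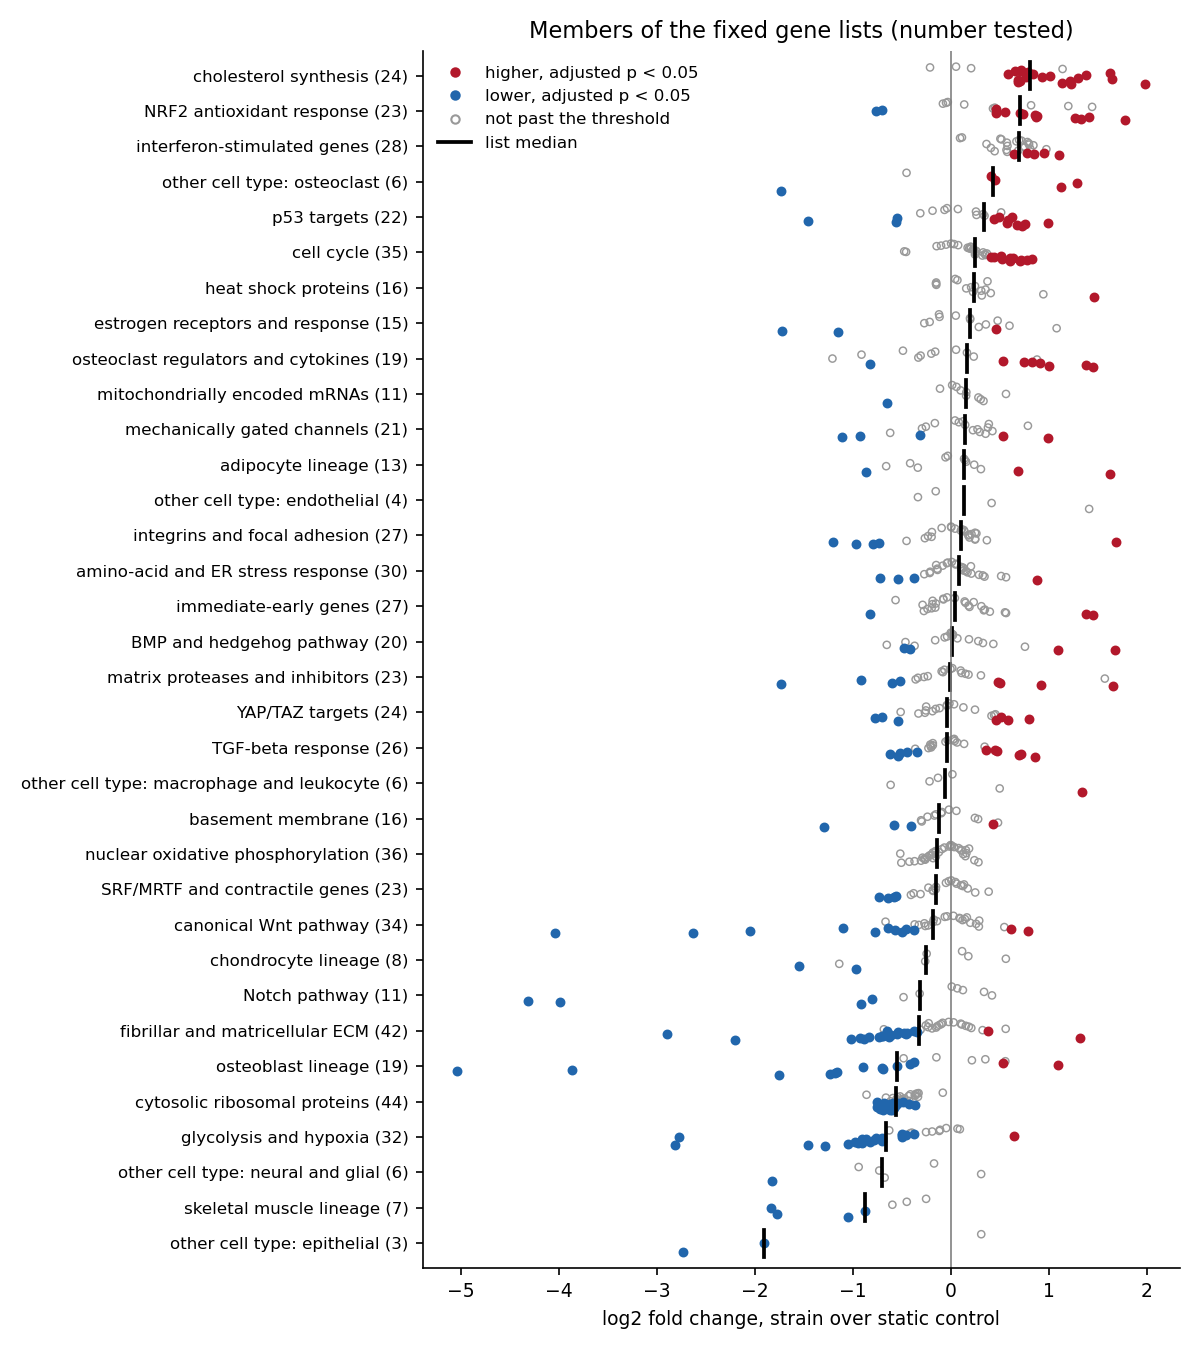
Log2 fold change (strain over static control, horizontal axis) of each tested member of the 34 fixed lists, in order of the list median (black line), with the number of tested members in brackets. Filled points passed an adjusted p of 0.05, red for higher and blue for lower, and the cholesterol synthesis list held 20 higher members of 24.

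Genes of the cholesterol synthesis list rose together: 20 of 24 tested members were higher and 0 lower, with a median log2 fold change of 0.81. Adjusted over the list alone the counts were also 20 and 0. Msmo1, a sterol oxidase gene, reached 32.8 ± 3.02 CPM against 14.1 ± 2.07 CPM (SD, n = 3), a 2.34-fold rise, and Insig1, a regulator of sterol sensing, rose 2.20-fold and the synthase gene Hmgcs1 1.60-fold. The list was called by camera (adjusted p = 2.08e-11), and with an estimated correlation it was not (adjusted p = 0.458). In the adipocyte list, 2 of 13 members rose and 1 fell, with counts of 3 and 1 adjusted over the list alone. The desaturase gene Scd1 rose 3.07-fold and the acyltransferase gene Dgat2 fell by 0.87 on the log2 scale, and camera gave an adjusted p of 0.556.

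Genes of the NRF2 antioxidant response were higher in 12 of 23 members and lower in 2, or 17 and 2 when adjusted over the list alone, with a median of 0.70. Nqo1 was at 62.6 ± 8.50 CPM against 18.2 ± 0.22 CPM (SD, n = 3), and the glutathione synthesis genes Gclc and Gclm rose 2.51-fold and 2.66-fold and the sulfiredoxin gene Srxn1 2.41-fold. The 2 lower members were the metallothionein genes Mt1 and Mt2 (log2 fold change −0.77 and −0.70), named after their values were seen. Both calls were lost without control replicate 1 or 3 or strain replicate 1 or 2 (adjusted p up to 0.0894 for Mt1 and 0.107 for Mt2), and without control replicate 3 the values were −0.51 and −0.45. Camera called it (adjusted p = 7.91e-06, and adjusted p = 0.607 with an estimated correlation). Strain replicate 1 had the highest CPM of 15 of the 23 members, and without it the median was 0.44. In the amino-acid and ER stress list 1 of 30 members rose, the cystine transporter gene Slc7a11 (1.84-fold), which the NRF2 list also holds, and 3 fell, with 3 and 3 adjusted over the list alone (camera adjusted p = 0.556). Among 16 tested heat shock genes 1 rose, Hsph1, at 216 CPM in strain replicate 1 and 70.0 and 67.1 CPM in the others, against 42.7 ± 2.33 CPM in controls (SD, n = 3). Its call was lost without control replicate 1 or 3 (adjusted p up to 0.0784), and its log2 fold change of 1.47 was 0.68 without strain replicate 1. The list was not called (adjusted p = 0.254) but passed without strain replicate 2 (adjusted p = 0.0298) or 3 (adjusted p = 0.0316), with 1 higher and 0 lower adjusted over the list alone.

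Cell cycle genes were higher in 11 of 35 members and lower in none, the same numbers as when adjusted over the list alone. They included Mcm2 (1.63-fold), Mcm3 (1.52-fold) and Mcm5 (1.72-fold), subunits of the replicative helicase, and the ribonucleotide reductase gene Rrm2 (1.64-fold). The median was 0.25 (camera adjusted p = 1.51e-05, and adjusted p = 0.607 with an estimated correlation). Of 22 targets of p53, 9 rose and 3 fell, or 12 and 4 adjusted over the list alone. Aen rose 1.66-fold, Ccng1 1.60-fold, Gtse1 1.69-fold and Eda2r 1.99-fold. Strain replicate 1 had the highest CPM of 12 of the 22 members. This list was called (adjusted p = 0.0222), and the call was lost with an estimated correlation (adjusted p = 0.607) and without strain replicate 1 (adjusted p = 0.158).

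Genes of the osteoblast lineage were lower in 12 of 19 tested members and higher in 2, with a median log2 fold change of −0.55. Sp7, the transcription factor of osteoblast commitment, fell from 31.8 ± 0.637 to 9.41 ± 2.18 CPM (SD, n = 3; log2 fold change −1.76, SE 0.17, adjusted p = 1.39e-04). Alpl, the alkaline phosphatase of mineralising cells, fell from 240 ± 11.9 to 102 ± 17.6 CPM, Omd from 39.9 to 17.6 CPM and the parathyroid hormone receptor gene Pth1r from 19.5 to 8.68 CPM. The 2 higher members were Bmp2 (log2 fold change 1.10) and Tnfrsf11b (0.53), the latter named after its value was seen, and the call of Bmp2 was lost without control replicate 1, strain replicate 2 or strain replicate 3 (adjusted p up to 0.0671). That of Tnfrsf11b was lost without control replicate 1 or 3 or strain replicate 2 or 3 (adjusted p up to 0.112). Adjusted over the list alone, 12 were lower and 3 higher. Camera called the osteoblast list (adjusted p = 2.81e-04, and adjusted p = 0.359 with an estimated correlation). Of 8 chondrocyte genes 2 fell, Col11a1 (log2 fold change −0.96) and Comp (−1.56), and 0 rose, with the same numbers adjusted over the list alone. Camera did not call that list (adjusted p = 0.258), and fry called it lower (adjusted p = 0.0228). Of 7 skeletal muscle genes 4 fell and 0 rose, with the same numbers adjusted over the list alone. Mef2c fell from 104 ± 9.81 to 50.1 ± 4.39 CPM (SD, n = 3), and the other 3, Tnnt1, Tnni1 and Des, were at 2.65 CPM or less in controls. The call of Tnnt1 was lost without control replicate 3 or strain replicate 3 (adjusted p up to 0.0754). That of Tnni1 was lost when any library other than strain replicate 3 was left out (up to 0.135). With 1 library left out, the Tnni1 log2 fold change of −1.84 lay between −2.80 (without strain replicate 3) and −1.51. The call of Des was lost when any of the 6 libraries was left out (up to 0.0999). The muscle list was called (adjusted p = 5.84e-04, and adjusted p = 0.359 with an estimated correlation).

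Fibrillar and matricellular matrix genes were lower in 20 of 42 members and higher in 2, with a median of −0.33, and counts of 22 lower and 4 higher adjusted over the list alone. The collagen-binding proteoglycan gene Fmod fell from 1787 ± 71.0 to 389 ± 56.4 CPM (SD, n = 3; log2 fold change −2.20, SE 0.12, adjusted p = 5.13e-06), Dcn from 144 to 71.1 CPM and Col16a1 from 166 to 90.1 CPM. Vcan, a large chondroitin sulfate proteoglycan gene, rose from 110 to 274 CPM (log2 fold change 1.32). Camera called the matrix list (adjusted p = 1.51e-05, and adjusted p = 0.607 with an estimated correlation). Of 16 basement membrane genes 3 fell, among them Col15a1 (295 to 120 CPM), and 1 rose (camera adjusted p = 0.357), with 5 and 2 adjusted over the list alone, and the list passed without control replicate 3 (adjusted p = 0.0247). Of 23 matrix proteases and inhibitors 4 rose and 4 fell (camera adjusted p = 0.960), with 5 higher and 7 lower adjusted over the list alone, a median of −0.0046 and a mean and test in the other direction (mean 0.03). The stromelysin gene Mmp3 rose 3.15-fold to 144 ± 12.9 CPM and the collagenase gene Mmp13 1.90-fold, while Mmp9 (log2 fold change −1.73) and Adamts5 (−0.60) fell. Of 27 integrin and focal adhesion genes 4 fell, including Itga10 (−0.97), Lims2 (−0.80) and Itga7 (−0.73), and 1 rose, with the same numbers adjusted over the list alone. Their median was 0.10 and their mean −0.03, and camera tended up (adjusted p = 0.988) and fry down.

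Hypoxia-response and glycolysis genes fell in 21 of 32 members, and 1 member rose, with a median log2 fold change of −0.67. Adjusted over the list alone, 23 were lower and 1 higher. The oxygen-sensing hydroxylase gene Egln1 fell from 308 ± 33.4 to 126 ± 2.19 CPM (SD, n = 3), Ankrd37 from 26.3 to 3.71 CPM, and the mitophagy receptor genes Bnip3 and Bnip3l from 212 to 77.2 CPM and from 202 to 97.7 CPM. The 1 higher member, named after its value was seen, was Hif1a, which encodes the oxygen-regulated transcription factor subunit (log2 fold change 0.64). Control replicate 3 had the highest CPM of 22 of the 32 members, and without it the median was −0.56. Camera called this list (adjusted p = 1.19e-10, and adjusted p = 0.359 with an estimated correlation). Of 36 nuclear oxidative phosphorylation genes 0 were called by edgeR, also adjusted over the list alone, 6 had an unadjusted p under 0.05, and DESeq2 called 1 and limma-voom 0 (median −0.14, camera adjusted p = 0.444). Of 11 mitochondrially encoded mRNAs 1 was lower, ND6 (adjusted p = 0.0401; 1 adjusted over the list alone). Camera gave an adjusted p of 0.379 for the list and 0.0241 without strain replicate 2, and the call of ND6 was lost with library size alone as scaling and without control replicate 1 or 3 or strain replicate 2 or 3 (adjusted p up to 0.135).

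Cytosolic ribosomal protein mRNAs were lower in 22 of 44 members and higher in 0, with a median of −0.56 and 44 of 44 fold changes below 0. Adjusted over the list alone, 41 were lower. Rpl7 fell from 1324 ± 232 to 818 ± 92.9 CPM (SD, n = 3) and Rpl10 from 458 ± 73.8 to 297 ± 28.1 CPM. Camera called the ribosomal list (adjusted p = 2.42e-11) but not with an estimated correlation (adjusted p = 0.607) or by fry (adjusted p = 0.0875). Control replicate 3 had the highest CPM of 43 of the 44 members, and without it the median was −0.36. Interferon-stimulated genes were higher in 5 of 28 members, or 21 adjusted over the list alone, with a median of 0.69 and 28 of 28 fold changes above 0. Gbp3 was at 50.2 ± 12.8 CPM against 23.4 ± 9.81 CPM and Gbp2 at 85.8 ± 14.8 CPM against 54.8 ± 11.3 CPM (SD, n = 3). Both lost their calls without control replicate 1 or 3 or strain replicate 1 or 2 (adjusted p up to 0.105). Strain replicate 1 had the highest CPM of 22 of the 28 members. The interferon list was called by camera (adjusted p = 1.97e-06) and not with an estimated correlation (adjusted p = 0.634) or by fry (adjusted p = 0.207).

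Of 21 mechanically gated channel genes 2 rose, Panx1 (1.99-fold) and Piezo1, and 3 fell, including Trpc6 (log2 fold change −1.12) and Kcnk2 (−0.93), with 3 and 3 adjusted over the list alone and a camera adjusted p of 0.573. Of 24 YAP/TAZ targets 4 rose and 3 fell, also adjusted over the list alone (camera adjusted p = 0.955), among them Crim1 (log2 fold change 0.80) and Tgfb2 (−0.54). The call of Crim1 was lost without control replicate 1, strain replicate 2 or strain replicate 3 (adjusted p up to 0.0843), and that of Tgfb2 without control replicate 1 or strain replicate 3 (up to 0.0700). Of 23 SRF and contractile genes 0 rose and 4 fell, or 6 adjusted over the list alone, among them the tropomyosin gene Tpm1 (903 to 580 CPM) and the myosin light chain gene Myl9 (183 to 110 CPM), with a camera adjusted p of 0.137, or 0.0462 without strain replicate 2. Of 27 immediate-early genes 2 rose, Ptgs2, the inducible cyclooxygenase (2.73-fold, to 98.4 ± 5.63 CPM), and Fosb (2.60-fold), and 1 fell, Klf2 (−0.83), the same numbers as adjusted over the list alone (camera adjusted p = 0.556). In the list of osteoclast regulators and cytokines, 7 of 19 members rose and 1 fell, or 8 and 2 adjusted over the list alone. The chemokine genes Ccl2 and Ccl7 rose 2.61-fold and 2.00-fold and the prostacyclin synthase gene Ptgis fell by 0.82 on the log2 scale, and camera gave an adjusted p of 0.119, which was 0.0353 without strain replicate 1 and 0.0479 with a minimum of 50 counts.

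Of 34 Wnt pathway genes 10 fell and 2 rose, or 10 and 3 adjusted over the list alone. The antagonist genes Dkk2 (7.90 to 1.27 CPM) and Nkd1 (2.12 to 0.129 CPM, with 232 and 15 summed counts, a ratio of 0.0607 with a 95% exact interval of 0.0334 to 0.102 for counting error only) and Tcf7l1 (41.5 to 24.2 CPM) and the receptor gene Fzd2 (141 to 99.6 CPM) were lower. Strain replicate 2 held 10 of the 15 strain counts of Nkd1, whose log2 fold change of −4.04 was −5.07 without it. With any 1 library left out, the log2 fold change of Nkd1 lay between −5.07 and −3.65. The camera call (adjusted p = 0.0439) was lost with an estimated correlation (adjusted p = 0.754), with fry (adjusted p = 0.0875), with a minimum of 50 counts (adjusted p = 0.0670) and without control replicate 2, strain replicate 1 or strain replicate 3 (adjusted p up to 0.352), and the median of −0.18 was −0.11 without control replicate 2. Of 26 TGF-beta response genes 6 rose, including Ltbp2 (1.81-fold), and 5 fell, with 6 and 6 adjusted over the list alone. Their median was −0.04 and their mean 0.0014, and camera tended down (adjusted p = 0.683). Of 11 Notch pathway genes 4 fell and 0 rose (5 adjusted over the list alone; camera adjusted p = 0.0772, which was 0.00678 without control replicate 3, 0.0377 without strain replicate 2 and 0.0165 without a filter), including the transcriptional repressor gene Hes1 (36.4 to 19.2 CPM). Of 20 BMP and hedgehog genes 2 rose, including Grem1, and 2 fell (3 and 3 adjusted over the list alone; camera adjusted p = 0.786). Of 15 genes of estrogen receptors and response, Igfbp4 fell from 612 ± 42.8 to 275 ± 27.5 CPM (SD, n = 3) and Gper1, a membrane estrogen receptor, from 4.64 to 1.40 CPM. Hsd17b12 rose 1.38-fold in the same list, a call lost without control replicate 1 or strain replicate 2 (adjusted p up to 0.0611), and 5 were higher and 2 lower adjusted over the list alone (camera adjusted p = 0.562).

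Markers of other cell types were mostly near or below the expression filter. Of 18 macrophage and leukocyte markers 6 were tested and 1 rose, Cd14 (7.01 to 17.7 CPM), and of 13 endothelial markers 4 were tested and 0 were called by edgeR, DESeq2 or limma-voom, with 1 at an unadjusted p under 0.05. Of 13 epithelial markers 3 were tested and 2 fell, Krt19 (24.5 to 3.68 CPM) and Cdh1 (7.57 to 2.02 CPM). Of 13 neural and glial markers 6 were tested and S100b fell from 15.6 to 4.40 CPM. The neural list was called (adjusted p = 0.0467), and this was lost with an estimated correlation (adjusted p = 0.458), without a filter (adjusted p = 0.268) and without control replicate 2, strain replicate 1 or strain replicate 3 (adjusted p up to 0.113). Of 11 osteoclast markers 6 were tested, 4 rose, among them Atp6v0d2 (2.95 to 6.40 CPM), and 1 fell, Mmp9 (camera adjusted p = 0.350). The calls of Tnfrsf11a and Nfatc1, also higher, were each lost in 5 of the 6 fits with 1 library left out (adjusted p up to 0.112 and 0.137). Adjusted over the list alone, the higher and lower members were 1 and 0 for macrophage, 0 and 0 for endothelial, 0 and 2 for epithelial, 0 and 2 for neural and 4 and 2 for osteoclast markers. Camera did not call the macrophage list (adjusted p = 0.452), whose median was −0.06 and mean 0.15, and fry called it higher (adjusted p = 0.00478).

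**Figure D2:**
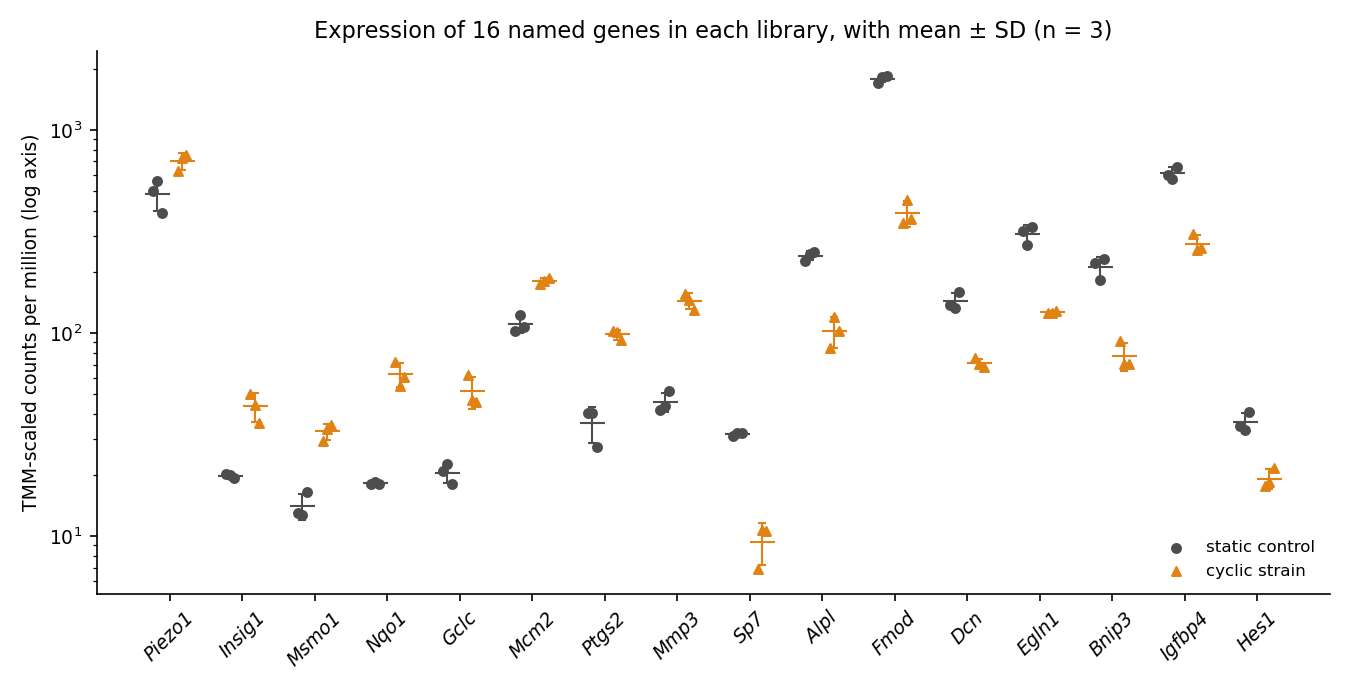
TMM-scaled CPM (vertical log axis) of 16 named genes in each static control (grey circles) and cyclic strain library (orange triangles), with the mean and SD of 3 libraries as bars. Piezo1 lay at 392 to 563 CPM in control and 627 to 751 CPM in strain libraries.

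The ATAC-seq comparison asked where accessible chromatin differs between control and Piezo1 knockout cells. Piezo1 lies on chromosome 8 from 122481698 to 122551329. A peak beyond the upper end of the gene was called in all 4 libraries, at 122556121 to 122557031 in control replicate 1, 122556163 to 122556801 in control replicate 2, 122556260 to 122556754 in knockout replicate 1 and 122556093 to 122556294 in knockout replicate 2. At the upper end of the gene, control replicate 1 had a peak at 122551427 to 122551637, control replicate 2 had peaks at 122550949 to 122551304 and 122551431 to 122551637, knockout replicate 2 had a peak at 122550984 to 122551642 and knockout replicate 1 had none in its list. Editing of the gene need not remove accessibility, so these peaks do not check the labels.

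Merging the lists gave 29289 regions, of which 7721 were found in all 4 libraries. In both control libraries and neither knockout library there were 3096 regions, and in both knockout and neither control library 459. With lists of equal length the numbers were 1619 and 1010. The other ways to pair the libraries gave 87 and 747 regions, or 48 and 1234, as deposited, and 227 and 462, or 273 and 386, at equal length. Without control replicate 1 the control-only count was 12341. The knockout-only count was 1869 without control replicate 2, 1357 without knockout replicate 1 and 2433 without knockout replicate 2. These counts let a group with 1 library left pass on that library alone. The Jaccard index was 0.450 between the controls, 0.516 between the knockouts and 0.379 to 0.437 between groups. A rearrangement of the libraries over 3 splits cannot pass a threshold of 0.05, and no test based on a model was made.

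**Figure D3:**
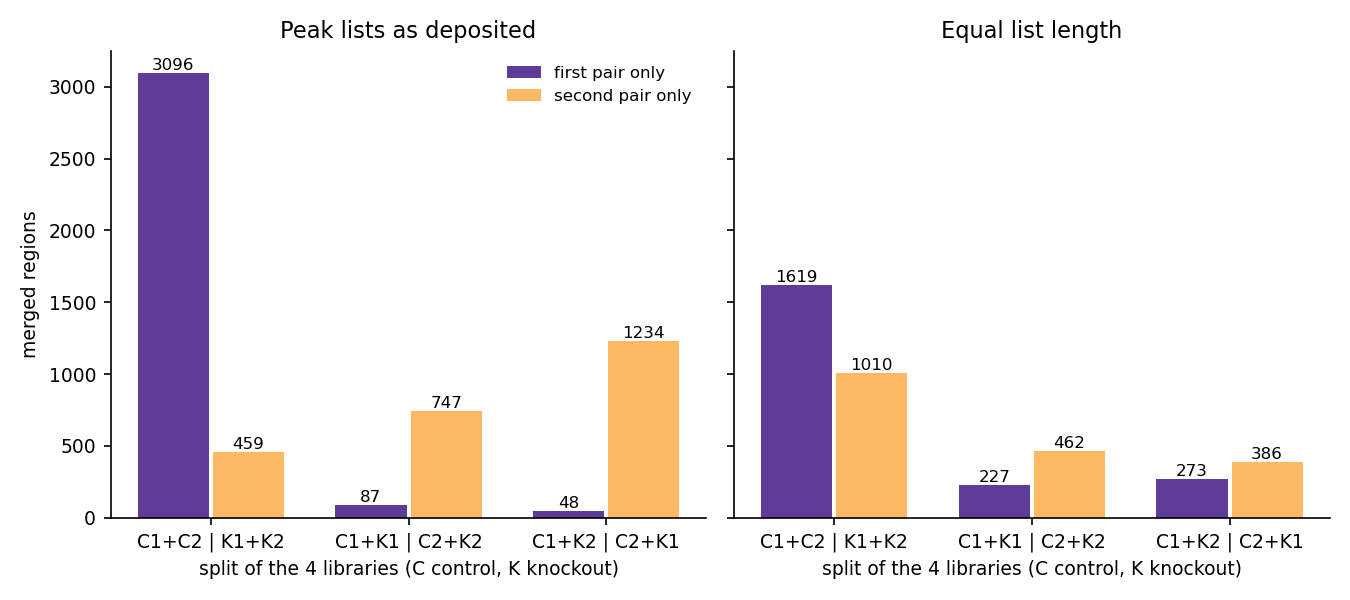
Number of merged regions found in both libraries of a pair and in neither of the other pair (vertical axis), for the 3 ways to split the 4 libraries, with the lists as deposited (left) and at equal length (right). The split by group gave 3096 and 459 regions as deposited and 1619 and 1010 at equal length.

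The control-only region with the highest lower −log10 q (24.1) lay on chromosome 11 from 110880849 to 110881717, between genes, with Kcnj16 the nearest protein-coding gene at 86316 bp. The next lay on chromosome 1 from 153572103 to 153573226, 22389 bp from Npl, on chromosome 8 from 84742045 to 84742779 within Nfix, on chromosome 5 from 104056041 to 104056498 within Nudt9, and on chromosome 16 from 25900289 to 25901121, 8201 bp from Trp63. The strongest knockout-only regions lay on chromosome 16 from 57927750 to 57928762 (lower −log10 q 17.5), 173013 bp from Col8a1, on chromosome 16 from 29816621 to 29817288, 153494 bp from Opa1, on chromosome 3 from 121521395 to 121522217 within Slc44a3, on chromosome 6 from 117319331 to 117320144, 137963 bp from Cxcl12, and on chromosome 6 from 50848115 to 50848766, 193670 bp from Npvf. Exons, introns and UTRs were not assigned, since only gene ends were used here.

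The share of peaks on whole chromosomes differed between the groups. Chromosome X held 1.78% and 1.96% of the peaks in control replicates 1 and 2 and 1.04% and 0.977% in knockout replicates 1 and 2, a ratio of 0.539. Chromosome 1 held 7.20% and 7.19% against 5.51% and 5.02%, and chromosome 15 held 5.91% and 5.33% against 4.39% and 4.49%. On chromosome 8 the shares were 4.79% and 5.06% in control and 6.22% and 6.34% in knockout libraries, and on chromosome 16 they were 3.29% and 3.38% against 4.32% and 4.36%. The groups did not overlap on 12 of 20 chromosomes, or on 14 at equal list length, where chance separates pairs of libraries on 1 in 3 chromosomes. The shares of a library are parts of 1 whole, so chromosomes are not independent and this count is no test. The other splits were not counted. Ratios varied between bins along chromosomes, which was not tested. The following 10 Mb bins were chosen after their log2 ratios of knockout over control were seen. On chromosome X the log2 ratio was 0.45 from 100000001 (0.21 between the controls and −0.20 between the knockouts). It was 0.33 from 130000001 (0.65 and −0.82), a bin where replicates differed by more than the groups. The other bins of X with enough peaks to be used lay at −1.96 to −0.59. On chromosome 15 the log2 ratio was −1.06 from 20000001 (0.07 and −0.09) and 0.06 from 80000001 (−0.27 and 0.21). All bins of chromosome 15 that start before 70000001 lay at −1.06 to −0.31. Those from 70000001 on lay at −0.19 to 0.06, a border chosen after the values were seen. Without chromosomes 1, 8, 15, 16 and X, an alternative chosen after seeing the data, 2249 control-only and 345 knockout-only regions were counted.

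**Figure D4:**
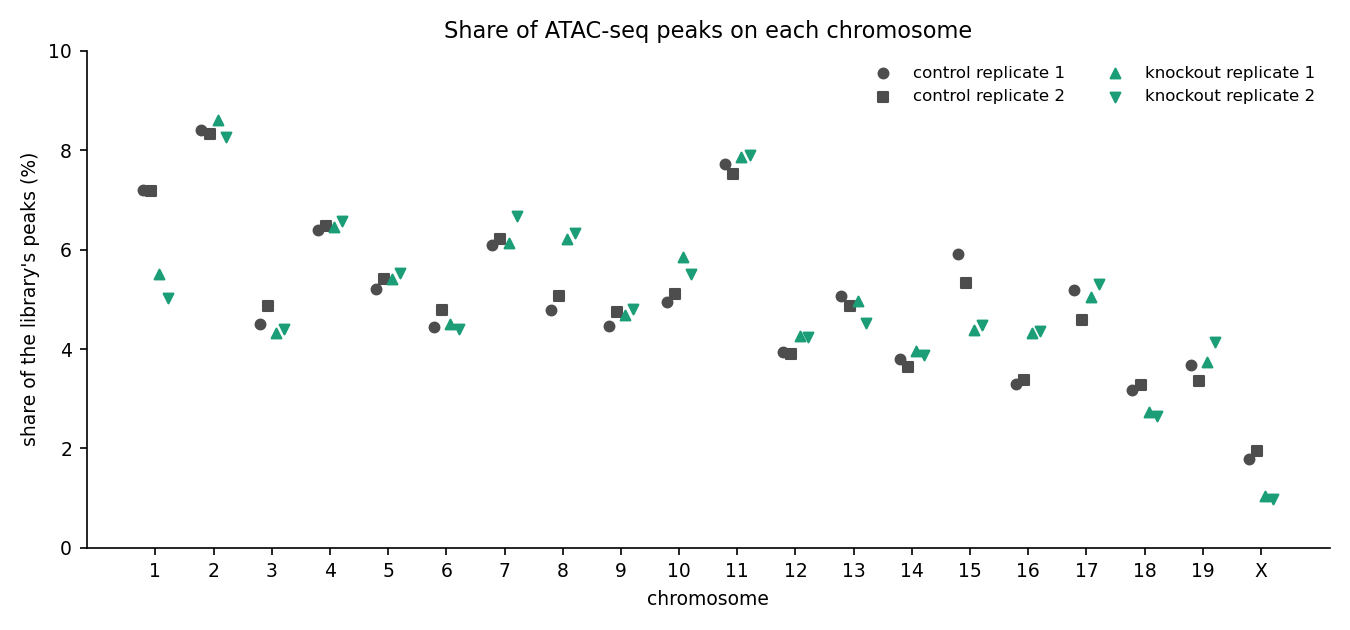
Share of each library's ATAC-seq peaks (vertical axis, %) on each chromosome (horizontal axis) in control replicates 1 and 2 (grey) and knockout replicates 1 and 2 (green). On chromosome X the control libraries lay at 1.78% and 1.96% and the knockout libraries at 1.04% and 0.977%.

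Group-specific regions lay away from gene ends more often than shared ones. Within 1 kb of either end of a protein-coding gene lay 59.3% of the regions in all 4 libraries, 18.5% of control-only regions (odds ratio 0.156) and 24.0% of knockout-only regions (odds ratio 0.217, Fisher's exact p = 2.98e-50). Regions are not replicates, so these tests describe the lists. Regions of the other splits were not compared, so the difference may hold for any region missing from some lists. It is not shown to be tied to the groups.

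Of the genes in the background, 19.3% lay near control-only regions, and 4 of 28 lists tested had a higher share past the adjusted threshold. They were 10 of 18 SRF and contractile genes (odds ratio 5.24, adjusted p = 0.0128, Fisher's exact test), 14 of 31 matrix genes (3.46, adjusted p = 0.0128), 11 of 23 integrin and focal adhesion genes (3.85, adjusted p = 0.0171) and 11 of 25 TGF-beta response genes (3.30, adjusted p = 0.0290). Lower shares with an unadjusted p under 0.05 were those of ribosomal protein genes (2 of 39, exact p = 0.0234, adjusted p = 0.131) and cell cycle genes (1 of 28, exact p = 0.0303, adjusted p = 0.141). Gene length and the number of regions per gene were not taken into account in these list tests. Genes are not replicates, and regions of the other splits were not tested against the lists. The higher shares may thus hold near any region missing from some lists, and they are not shown to be tied to the groups. With a window of 50 kb, 2 lists were called, SRF and contractile genes (adjusted p = 0.0261) and integrins (adjusted p = 0.0467). With lists of equal length, 4 lists were called, of which SRF and contractile genes and matrix genes (adjusted p = 0.00743 each) were also called with the lists as deposited, and YAP/TAZ targets (0.0338) and basement membrane genes (0.00743) were not. Integrins then had an adjusted p of 0.0567 and TGF-beta response genes, at 4 of 23 (odds ratio 1.60), an adjusted p of 0.612. List genes with the strongest control-only regions were the matrix genes Plod1, Col12a1 and Fbn1, the adhesion gene Tns1, Osgin1, Mef2c, Myof, Vwf, Filip1l and Runx2, the master regulator of osteoblasts, with a region on chromosome 17 from 44500194 to 44501004. No list was called near knockout-only regions in these Fisher's exact tests, where the unadjusted p was under 0.05 for chondrocyte genes (2 of 6, exact p = 0.0169) and p53 targets (3 of 15, exact p = 0.0144), each with an adjusted p of 0.236. The strongest such genes were Bbc3, Adamts1, Sesn2, Rpl6, Sox5, Zfp423, Osgin1, Rpl14, Il34 and Vegfa.

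Genes higher under strain lay near control-only regions more often than other genes, at 170 of 618 against 109 by chance (27.5% against 16.9%, odds ratio 1.87, Fisher's exact adjusted p = 9.53e-10). Genes lower under strain did so in 123 of 600 (20.5% against 17.4%, odds ratio 1.23, exact adjusted p = 0.105). The latter passed with a −log10 q of at least 5 (odds ratio 1.37, exact adjusted p = 0.00754) and within 3 classes of gene length (odds ratio 1.36, Mantel-Haenszel adjusted p = 0.00951), the latter an alternative chosen after seeing the data. The difference between the 2 directions was not tested. Near knockout-only regions lay 27 of the higher and 17 of the lower genes, against 20.1 and 19.5 by chance (odds ratios 1.39 and 0.860, exact adjusted p = 0.168 and 0.635). These uncalled directions turned, to 0.934 for higher genes with windows of 50 kb, and for lower genes to 1.05 with windows of 50 kb, 1.43 with a −log10 q of at least 5 and 1.31 at equal list length. The median gene length was 35.3 kb for higher, 16.8 kb for lower and 23.4 kb for other genes, and within the 3 length classes the odds ratio of higher genes near control-only regions was 1.63. The RNA-seq set holds no knockout and the ATAC-seq set no strain, so the overlap joins separate experiments. Genes are not replicates, and the region classes rest on 2 libraries per group, so these tests describe the lists. The number of regions per gene was not taken into account. Regions of the other splits were not compared, so the overlap is not shown to be tied to the groups.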

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

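The settings that left out chromosomes, used gene-length classes, used gene ends in place of start sites or tested gene lists at equal list length were chosen only after seeing the data. Counts of higher and of lower genes stayed within 1.5 times those reported with RLE scaling, library size only, the filter at 50 counts, DESeq2 and limma-voom. Without a filter 1428 genes were higher, with more genes tested, and at an absolute log2 fold change of at least 1 the counts were 170 and 383, by construction a part of the calls. Leaving out 1 library gave 369 to 1085 higher and 577 to 1244 lower genes. The replicate numbers did not clearly pair the libraries: deviations of same-numbered libraries correlated at 0.03, 0.21 and 0.09. Each control correlated best with the strain library of its own number, while strain replicate 1 correlated best with control replicate 3 (0.0905). Whether the numbers mark a pairing stays open. With the number as a block, 1557 genes were higher and 1619 lower, and 10 lists were called, with the calls of the Wnt (adjusted p = 0.145) and neural (adjusted p = 0.0891) lists lost. No paired analysis of the counts of regions was possible because they come from no test. The chromosome shares could be compared within replicate numbers, which was not done. List calls numbered 0 with an estimated correlation and 10 to 16 without 1 library. Of 123 named genes, 34 lost their call without 1 library, 3 lost it with library size only and 0 reversed. The log2 fold change of Piezo1 lay between 0.40 and 0.65 without 1 library.

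Equal list length, which by construction shortens the longer lists, gave 1619 control-only and 1010 knockout-only regions, or 1143 and 752 without chromosomes 1, 8, 15, 16 and X. Requiring a peak to cover 50% of the region left 4648 regions in all 4 libraries. Without 1 library, control-only regions numbered 3954 to 12341 and knockout-only regions 526 to 2433. With 50 kb windows, 2 lists were called near control-only regions. The odds ratio of genes higher under strain near knockout-only regions, not past the threshold, turned to 0.934 with 50 kb windows. That of lower genes turned to 1.05 with 50 kb windows, 1.43 at a −log10 q of 5 and 1.31 at equal length, also not past the threshold. For lower genes near control-only regions it passed at a −log10 q of 5 (1.37) and within length classes (1.36). Where no construction is named, the cause was not tested. The depth of the ATAC-seq libraries is unknown, which limits what a peak missing from a list can show.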

Other observations

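The tests of the ribosomal protein genes and of neighbouring chromosome bins were chosen only after the result was seen. Lysosomal genes outside the fixed lists, listed before their values were seen, rose under strain in 15 of 42 members and fell in 2, with a median log2 fold change of 0.22 (camera p = 1.23e-06, and p = 0.0766 with an estimated correlation). Among the higher were Npc1, a cholesterol exporter of the lysosome (0.92), the sulfatase gene Sgsh (0.82) and the proton pump subunit genes Atp6v1a (0.61) and Atp6v1b2 (0.60), and the lower included the cathepsin gene Ctsh (−0.47). The values go with a rise of the lysosomal gene group as a hypothesis, and the call did not hold with an estimated correlation. The list was not refitted with a library left out.

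The lower level of glycolysis and hypoxia mRNAs under strain was weighed against the scaling of the libraries and against reduced expression of targets of HIF, the oxygen-regulated transcription factor. The list median was −0.61 with library size only and −0.67 with RLE, so the choice among these scalings did not produce the lower level. The median log2 fold change over all genes was 0.0049 with TMM, 0.004 with RLE and 0.0548 with library size only. These scalings thus differed little, and the comparison could not decide on an error they share. A further 21 tested HIF targets, listed before their values were seen, held 14 lower and 0 higher members, among them Hilpda (−1.79), Higd1a (−1.21) and Rcor2 (−1.21), with a median of −0.62 (camera p = 4.29e-10, and p = 0.00239 with an estimated correlation). These values are consistent with reduced HIF target expression in strained cells, as a hypothesis. The further targets were measured in the same 6 libraries that gave the pattern, so they are no independent evidence for it. Their list was not refitted with a library left out. Medium depth, oxygen and cell density of moving and static plates were not measured and stay open.

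The lower ribosomal protein mRNAs were set against an equal loss of short abundant mRNAs and against the deviating control replicate 3. The ribosomal median minus that of nuclear oxidative phosphorylation genes was −0.42, and taken within each library it was 0.16 to 0.26 in controls and −0.29 to −0.11 under strain (difference −0.44, SE 0.06, n = 3 each), which argues against an equal loss. Without control replicate 3 the median was −0.36, which argues against that library as the whole of the difference, though it contributed to its size. Reads shared with pseudogenes and a biological difference between strained and static cells were not tested and stay open.

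The chromosome-wide difference in the peak lists was weighed against unequal list length and against copy number. With lists of equal length the log2 ratios of knockout over control shares still spanned 1.19, against 0.203 and 0.272 between replicates, which argues against list length. Ratios of neighbouring 10 Mb bins correlated at 0.52 over 240 pairs (one-sided permutation p = 1e-04, the smallest that 10000 permutations can give), against 0.18 and 0.09 between replicates, and at 0.07 (p = 0.113) with chromosome means removed. A copy-number difference of whole chromosomes or long segments could give this, but it cannot be told apart from differences in accessibility, since whole-chromosome ratios alone fix the correlation and peak lists hold no read depth. Ratios along chromosomes X and 15 varied between the bins picked, which was not tested, and a biological difference through the loss of Piezo1 stays open.

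For genes past the threshold, 1 of the 10 splits of the 6 RNA-seq libraries into 3 and 3 gave as many as the real 2045, with 0 the highest of the others. For gene lists, 3 of the 10 splits gave as many as the real 12, with 14 the highest and 4 the lowest of the others. With 10 splits the share cannot fall under 0.1.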
